A study of Mus musculus with 12 samples.

How the data were processed

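The series holds RNA sequencing of mouse tibialis anterior, a shin muscle, that carried either a GFP control vector or a vector expressing Crtc2, a coactivator of the transcription factor Creb1. The mice were fed ad libitum or went through 3 rounds of alternate day fasting (ADF). The labels give C57BL/6 males aged 13 weeks and 12 libraries in 4 groups of 3: ADF GFP, ADF Crtc2, fed GFP and fed Crtc2. Per the labels' protocols, RNA was extracted with TRIzol and cleaned on RNeasy columns, and the protocols name both an NEBNext Ultra II directional kit and an Illumina TruSeq Stranded mRNA preparation, without saying which libraries were made with which. The labels do not say that the libraries of a group come from separate animals, so the p-values measure the spread between these libraries, which may be technical. Nor do they say whether GFP and Crtc2 muscles were taken from the same animals, and the tests treat them as unpaired. The labels give no batch or date, and 0 columns of the table belonged to no sample.

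The deposited values are raw read counts per Ensembl gene, whole numbers without normalization. The submitters' processing notes name HISAT2 2.0.5, SAMtools 1.7, featureCounts of Subread 1.6.1 and DESeq2 1.18.1, with the builds GRCm38 and mm10, and do not state the role of each tool, the annotation release, the strand setting or how duplicates were treated. Gene positions are from GENCODE mouse release 21 on GRCm38, in which 99.9% of the 22607 genes were found (22582). Total counts per library ranged from 24232450 to 34610417, so that 3 counts in a library, the floor used for a gene at 0, correspond to 0.0814 to 0.13 counts scaled to library size (CPM). Between 68.9 and 74.7% of the counts from 2 to 21 in each library were even numbers, which would arise if fragments were often counted 2 times. The cause was not tested, and if so, low counts and the floor of 3 counts stand for fewer fragments than printed. Among the 2318 genes with a mean of 1 to 3 CPM, 4.8 to 35.9% of the values in a library were 0, where Poisson counting would give 6.07e-11%. The floors cover counting error only, and the spread between libraries is wider. The 95% intervals in the closing section are over genes, from 10000 bootstrap resamples or 10000 random lists, and do not cover the spread between libraries. Within each group no library was a duplicate of another, and pairs from different groups were not compared in this way.

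Changes between groups were tested with edgeR 4.0.16 in R 4.3.3: trimmed mean of M values (TMM) scaling, genes kept by filterByExpr over the 4 groups (16007 genes), a quasi-likelihood fit with robust spread estimates over all 12 libraries with the 4 group means as terms, and Benjamini-Hochberg adjustment over the genes tested, with a threshold of 0.05. There were 5 comparisons: Crtc2 against GFP in fed muscle and under ADF, ADF against fed in GFP muscle and in Crtc2 muscle, and the diet by vector interaction, which is the response to Crtc2 under ADF minus that in fed muscle. Adjusted p-values in the text are from this test unless another tool is named. Errors of log2 fold changes are standard errors, computed as the log2 fold change divided by the square root of its F statistic. Levels are mean CPM with TMM-scaled library sizes ± SD over 3 libraries, and a prior count of 2 was used for log CPM. A fold against a group at 0 in all its libraries was computed against the floor of 3 counts per library. It is a lower bound for counting error alone, not for the wider spread between libraries, and "at least" refers to this floor. The smallest two-sided exact p that 3 against 3 libraries allow is 0.1, so a gene alone could not pass an exact test.

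Before the data were examined, 42 gene lists were fixed, of which 41 had at least 3 measured members and were tested (639 of 663 genes measured). Each was tested with camera in limma 3.58.1 against all other genes tested, with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. The test was repeated with the correlation estimated from the data, and with fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes. Calls that rest on the preset correlation alone are given with their adjusted p at an estimated correlation. Counts of list members are given over all genes tested and adjusted over the list alone.

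The genes named in the text follow a rule that was also fixed before the data were examined. It takes Crtc2 and the tested members of the CRTC and CREB family; for each of the 4 comparisons of 2 groups, the 10 largest rises and 10 largest falls among genes past the threshold whose 3 against 3 values do not overlap and whose mean is at least 2 CPM, without predicted or unnamed genes; for the interaction, 5 each way past the threshold, of which there were 0; for each list, up to 4 members with the smallest adjusted p and more where they passed; and 20 genes named whatever their result. Not every gene under this rule is named. List members left out for length were chosen after their values were seen, and in the comparison of ADF with feeding in GFP muscle they include several whose call was lost with 1 library left out. The text says where a gene outside the rule was chosen after its values were seen. Crybg3 has 2 entries in the table, and the one named here has no match in the annotation used.

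The alternatives tried were relative log expression (RLE) and upper-quartile scaling, scaling by library totals without the 20 most abundant genes and Crtc2, no filter, a filter of 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, spread estimates that are not robust, a fit on the 6 libraries compared, a term for the replicate number, leaving out each library in turn, and an unadjusted p of 0.01 for the overlap of responses. Added after seeing the data were a filter at a mean of 10 CPM, the CRTC and CREB family without Crtc2, and list tests leaving out each library. A named gene's change of sign counts as a reversal where the gene passed in either fit or moved by more than 1 SE. Replicate numbers did not pair the libraries of different groups (correlations of -0.193 to 0.157), so the fit with a term for them was used only as an alternative. This does not exclude a pairing within animals in another order, for which no test was made and under which the p-values of Crtc2 against GFP would not hold as given. Sequences shared between transcripts were searched with blastn 2.17.0, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

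The tests were checked on simulated data with the depth and spread of these libraries, in which 100 genes changed 2-fold and 100 changed 4-fold. The edgeR test called between 1 and 12 of the 2-fold and between 22 and 44 of the 4-fold changes, with 0 to 5 false calls per comparison. DESeq2 called more of them, and 53 to 80 false genes of 107 to 142 calls in the comparisons of 2 groups and 45 of 75 in the interaction; limma-voom made 1 to 3 false calls. In simulated lists, 5 of 5 raised lists were called and 0 of the others, with the preset and with the estimated correlation. The simulated genes varied independently, so this says nothing on errors of the list tests where genes move together. Nor did the simulated libraries differ in the detection of low genes as the real ones did, so the counts of false genes may not carry over. Other splits of the real libraries called up to 23 genes in fed muscle and 71 in the interaction with edgeR. The lists were drawn from genes with a mean of at least 5 CPM and raised 1.5-fold, or from genes of at least 50 CPM and raised 2-fold. An earlier version of this simulation, also with a 1.5-fold rise, recovered 0 of 5 lists. The cause of the difference was not established. No library was left out of the tests reported.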

Results

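RNA of tibialis anterior muscle was sequenced in 12 libraries, 3 each from fed GFP, fed Crtc2, ADF GFP and ADF Crtc2 muscle, with 24232450 to 34610417 counts per library. Between 14313 and 17226 genes were detected in a library, and 16007 of the 22607 genes in the table were tested. The first principal component held 46.8% of the variance and parted the diets: ADF libraries lay between -38.3 and -18.2 and fed libraries between 16.9 and 37.2. The title of the series concerns activation of the Crtc2 and Creb1 network in muscle during intermittent fasting. The comparisons ask what ADF changes in muscle with each vector, what Crtc2 changes under each diet, and whether the response to Crtc2 differs between diets.

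The comparison of ADF with feeding in GFP muscle asks how control muscle differs between the diets. The protocols name 2 preparation kits without assigning them to libraries. A preparation difference that followed the diets thus cannot be told apart from fasting in either comparison of ADF with feeding. Several genes of fat use and fuel choice were higher under ADF. Pdk4, the kinase that shuts off pyruvate dehydrogenase (chromosome 6, 5483351 to 5496309), rose 9.9-fold, from 208 ± 129 to 2059 ± 254 CPM (SD, n = 3 each). Its log2 fold change was 3.31 ± 0.51 (SE, as for all that follow), with an adjusted p of 0.00286. Pnpla2, the lipase that starts triglyceride breakdown, rose 4.61-fold, from 169 ± 4.16 to 780 ± 195 CPM. The PPAR targets of fasting had a median log2 fold change of 1.83 (adjusted p = 2.55e-08, and 0.00854 with an estimated correlation): 5 of 12 measured members rose, 6 when adjusted over the list alone, and 0 fell. Among them were Ucp2 (2.06 ± 0.33) and Ucp3 (1.32 ± 0.30), mitochondrial carriers, Acot2 (1.74 ± 0.34), a mitochondrial acyl-CoA thioesterase, and Vldlr (1.30 ± 0.20), a lipoprotein receptor. In the list of lipolysis and lipid droplets, 7 of 16 members rose and 1 fell, with 8 and 3 when adjusted over the list alone (adjusted p = 2.35e-06, and 0.0364 with an estimated correlation). Gpam, which starts glycerolipid synthesis, rose by 2.26 ± 0.26, and Plin4 (1.57 ± 0.21) and Plin5 (1.66 ± 0.34), which coat lipid droplets, rose too. Of 24 fatty acid oxidation genes 11 rose and 1 fell, with 14 and 1 over the list alone (adjusted p = 3.57e-07, but 0.365 with an estimated correlation). Acsl1, which activates fatty acids, rose by 1.85 ± 0.23, Acadvl, the very long chain acyl-CoA dehydrogenase, by 1.34 ± 0.23, and Mlycd, the malonyl-CoA decarboxylase, by 1.20 ± 0.21. Lpl, the lipoprotein lipase, rose by 0.91 ± 0.20, and Etfb, an electron carrier of this pathway, fell by 0.95 ± 0.21. Without ADF GFP replicate 2 the adjusted p of Lpl was 0.0529, and without ADF GFP replicate 1 that of Ucp3 was 0.0588.

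Some genes of protein breakdown rose in GFP muscle, and the proteasome list did not pass (median 0.03, 3 of 26 up and 1 down, as over the list alone; adjusted p = 0.84). Fbxo32, the muscle ubiquitin ligase atrogin-1 (chromosome 15, 58175879 to 58214932), rose 6.98-fold, from 106 ± 23.5 to 740 ± 103 CPM (2.80 ± 0.27, adjusted p = 2.93e-06). The list of ubiquitin ligases and FoxO atrophy genes had 8 of 17 members up, 11 over the list alone, and 0 down (median 1.08, adjusted p = 3.71e-10, and 0.0226 with an estimated correlation). It includes Trim63, the ligase MuRF1 (1.45 ± 0.33), Klf15, a transcription factor induced by glucocorticoids (1.99 ± 0.29), and Ddit4, an inhibitor of mTORC1 (1.86 ± 0.39). Of 15 glucocorticoid targets 5 rose, 6 over the list alone (adjusted p = 1.55e-05, and 0.0524 with an estimated correlation). Among them were Klf9 (2.37 ± 0.27), Cebpd (2.26 ± 0.45), Fkbp5 (2.38 ± 0.58) and Glul, the glutamine synthetase (1.39 ± 0.26). Of 23 autophagy and lysosome genes 6 rose, 10 over the list alone (adjusted p = 9.08e-05, and 0.0518 with an estimated correlation). The autophagy kinase Ulk1 rose by 1.44 ± 0.27 and the cargo receptor Sqstm1 by 0.96 ± 0.18. Of 17 genes of glycogen metabolism 8 rose, 11 over the list alone (adjusted p = 1.94e-06, and 0.111 with an estimated correlation). They include the glycogen synthase Gys1 (1.56 ± 0.18) and the lysosomal glucosidase Gaa (2.04 ± 0.31). CREB and CRTC target genes were higher as a list, with 3 of 24 members up, 4 over the list alone, where 1 fell (median 0.61, adjusted p = 0.000258, and 0.0297 with an estimated correlation). The 3 were Pde4d, a cAMP phosphodiesterase (2.07 ± 0.24), the insulin receptor substrate Irs2 and the nuclear receptor Nr4a3 (4.05 ± 1.04). Atf1, a relative of Creb1, rose by 2.12 ± 0.47, with the 1 passing member of the 7 in the CRTC and CREB family (3 over the list alone; adjusted p of the list = 0.074). Leaving out Fed GFP replicate 1 took the adjusted p of Trim63 to 0.0715 and that of Fkbp5 to 0.147, and leaving out Fed GFP replicate 3 took that of Nr4a3 to 0.145.

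Nuclear genes of oxidative phosphorylation were lower as a list in GFP muscle under ADF: 16 of 48 fell and 2 rose, with 21 and 4 over the list alone (median -0.38, adjusted p = 2.47e-07, but 0.582 with an estimated correlation). Cox7a1 fell by 1.11 ± 0.19 and Cox8b by 1.00 ± 0.17, both parts of cytochrome oxidase. Ndufa2 of complex I fell by 0.98 ± 0.19, while Sdha of complex II rose by 0.91 ± 0.18. Log2 fold changes in this comparison rose with gene length (Spearman's rho 0.173 over genes with a mean of at least 10 CPM). The list was not compared with genes of like length here, so the part of length in its fall was not tested. Of 17 genes of the tricarboxylic acid (TCA) cycle 5 rose, 7 over the list alone, and 0 fell (adjusted p = 0.00208, but 0.669 with an estimated correlation). Ogdh rose by 1.39 ± 0.18. Of 21 genes of the extracellular matrix 2 rose, Mmp2 (1.37 ± 0.24) and Fn1 (1.48 ± 0.36), and 4 over the list alone (adjusted p = 5.22e-05, but 0.582 with an estimated correlation). The list medians of macrophage markers (0.70, 0 of 15 past the threshold, 4 over the list alone) and fibroblast markers (0.70, 3 of 10 up, also over the list alone) were higher too, each with an adjusted p of 0.0132, but 0.327 and 0.283 with an estimated correlation. Slow fibre genes were lower as a list (median -0.64, 1 of 10 down, 2 over the list alone; adjusted p = 0.0463, but 0.506 with an estimated correlation). The list of branched-chain amino acid (BCAA) catabolism (2 of 17 up, 4 over the list alone; adjusted p = 0.0416, but 0.65 with an estimated correlation) lay near the threshold. So did that of insulin, IGF and myostatin signalling (1 of 18 up and 1 down, as over the list alone; adjusted p = 0.0489, but 0.207 with an estimated correlation). Leaving out 1 library ended the calls of the slow fibre list (adjusted p = 0.34 without Fed GFP replicate 1), BCAA catabolism (0.269 without Fed GFP replicate 1). It also ended those of the fibroblast list (0.129 without Fed GFP replicate 2), the insulin list (0.0835 without Fed GFP replicate 3) and the macrophage list (0.0811 without ADF GFP replicate 3). Without Fed GFP replicate 1 the adjusted p of Fn1 was 0.0974.

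The largest changes in GFP muscle involved genes that were near 0 under 1 diet. Irs2 (chromosome 8, 10984681 to 11008458) was at 0 counts in the 3 fed libraries and at 12.7 ± 3.71 CPM under ADF, at least 118-fold higher by the floor of 3 counts per library. The same bound was at least 74.9-fold for the protocadherin Pcdhgc3, 55.4 for Vash1, 52.8 for Ccdc85c, 51.6 for Cyp26b1, which degrades retinoic acid, 48.1 for Crybg3 and 37.7 for Dpyd. Lyve1, a marker of lymphatic vessels and resident macrophages, had 1 count in the fed and 435 in the ADF libraries, Cyp2e1 had 4 and 730, and Pm20d2 had 8 and 1203. Among genes with a mean of 1 to 3 CPM, 12.1 to 32.7% of values were 0 in the fed GFP libraries. In the ADF GFP libraries it was 5.9 to 19.4%. The part of this difference in detection in the genes near 0 in fed muscle was not tested. Of the genes that fell, the sperm channel gene Catsper4 had 375 counts in the fed and 4 in the ADF libraries, Dcdc2b 650 and 11, and Spag1 764 and 14, while Spaca6 fell by 4.55 ± 1.28. Neat1, the scaffold RNA of nuclear paraspeckles (chromosome 19, 5824708 to 5845478), fell 11.4-fold, from 1654 ± 180 to 145 ± 28.7 CPM (adjusted p = 1.25e-09). Meg3, an imprinted noncoding RNA, fell by 3.45 ± 0.64, the RNA gene Snhg20 by 3.85 ± 0.79, Sec14l5 by 3.60 ± 0.45 and Rsrp1 by 3.41 ± 0.19, from 697 ± 75.3 to 65.5 ± 13.7 CPM. AI480526 fell by 5.15 ± 0.79. Leaving out 1 library ended the call of 7 of these. The adjusted p was 0.0725 for Dpyd without ADF GFP replicate 2, and 0.0577 for Lyve1 and 0.169 for Catsper4 without ADF GFP replicate 3. It was 0.0853 for Pm20d2 and 0.0947 for Dcdc2b without Fed GFP replicate 1, and 0.132 for Spaca6 and 0.0924 for Spag1 without ADF GFP replicate 1. Overall counts: 1140 genes passed, 650 higher (57%) and 490 lower, 739 of them at least 2-fold. Scaling by library totals, which shifts the median of all genes by -0.16, gave 444 higher of 1195 (37.2%), DESeq2 943 of 1898 (49.7%) and a filter at a mean of 10 CPM 626 of 1375 (45.5%), so the split by direction rests on the scaling, the tool and the filter. The count was 677, 711 and 740 without ADF GFP replicates 2, 1 and 3.

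Of the 20 genes named in advance, Cpt1b (0.83 ± 0.52), Angptl4 (1.92 ± 1.19), Fasn (0.85 ± 0.47), Ppargc1a (0.51 ± 0.38), Nr4a1 (0.62 ± 0.24), Sik1 (0.23 ± 0.40), Adipoq (1.89 ± 1.86), Igf1 (-0.10 ± 0.83), Myh7 (-0.21 ± 0.84), Myh4 (-0.28 ± 0.37), Mki67 (-1.22 ± 1.13), Myh3 (-1.13 ± 0.49) and Crtc2 itself (-0.24 ± 0.27) did not pass in GFP muscle.

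**Figure D1:**
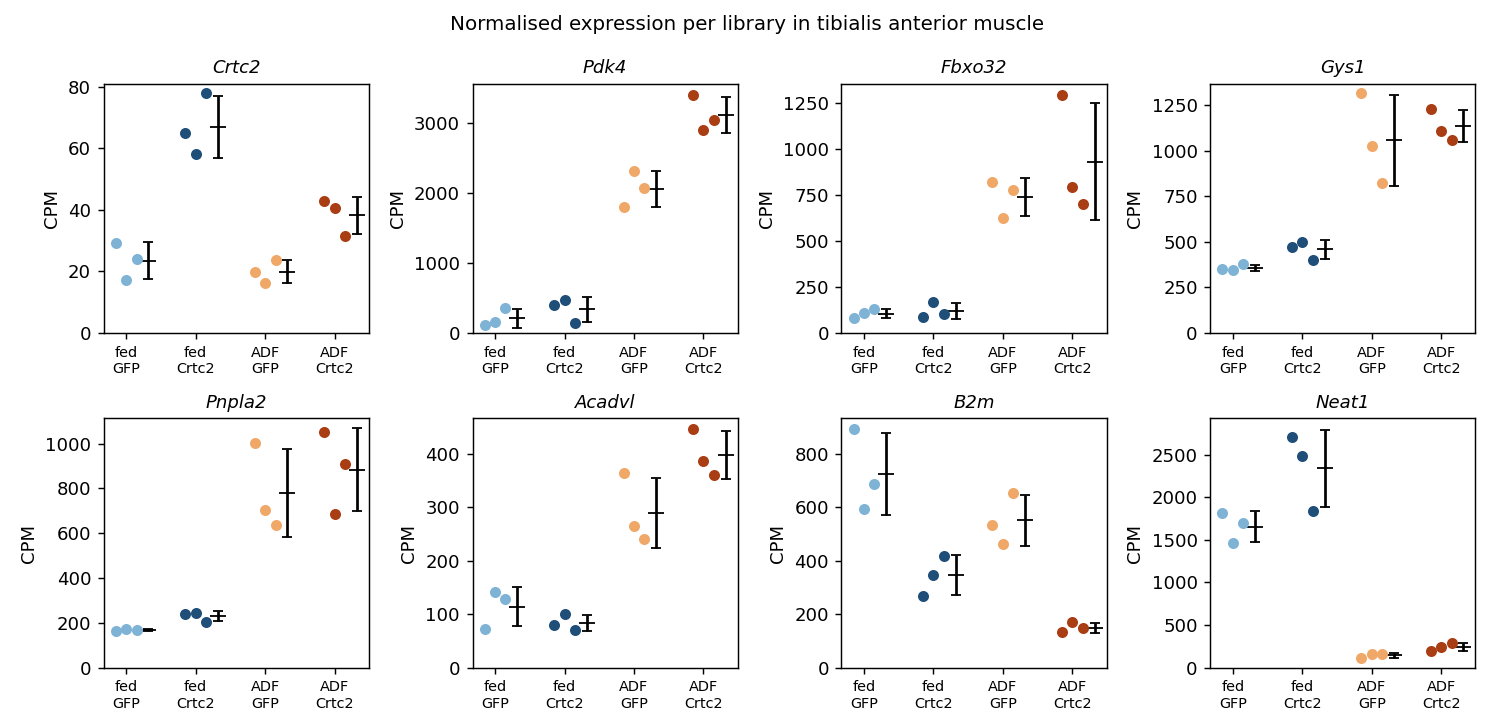
Levels (CPM) of 8 genes in each of the 12 libraries (dots), with the mean and SD of each group of 3 (bars). Crtc2 was at 67.0 ± 10 in fed Crtc2 and 23.5 ± 5.97 CPM in fed GFP muscle, Pdk4 averaged 2059 CPM in ADF GFP and 3113 CPM in ADF Crtc2 muscle, and B2m averaged 150 in ADF Crtc2 and 551 CPM in ADF GFP muscle.

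In Crtc2 muscle, the comparison of ADF with feeding asks how muscle with added Crtc2 responds to fasting. Many of the genes of fuel use tested, though not all, were higher under ADF. Pdk4 rose 9.16-fold, from 340 ± 178 to 3113 ± 257 CPM (3.20 ± 0.50, adjusted p = 0.00219), and Fbxo32 7.76-fold, from 120 ± 44.5 to 931 ± 319 CPM (2.96 ± 0.28). Of 24 fatty acid oxidation genes 16 rose and 1 fell, with 20 and 1 over the list alone (median 0.92, adjusted p = 1.6e-17, but 0.0949 with an estimated correlation). Acadvl rose by 2.24 ± 0.24, Acsl1 by 2.0 ± 0.23, Mlycd by 1.71 ± 0.21, Lpl by 1.21 ± 0.21 and Etfdh, which passes electrons to ubiquinone, by 1.76 ± 0.24. Lipolysis and lipid droplet genes had 9 of 16 members up, with 10 up and 1 down over the list alone (adjusted p = 8.24e-08, and 0.0246 with an estimated correlation). Among them were Pnpla2 (1.94 ± 0.20), Gpam (2.5 ± 0.26), Plin5 (2.51 ± 0.35) and Dgat2, which makes triglycerides (2.61 ± 0.53). Of 12 PPAR targets of fasting 4 rose, 5 over the list alone (adjusted p = 1e-06, and 0.0116 with an estimated correlation). Ucp3 rose by 1.61 ± 0.31 and Acot2 by 2.13 ± 0.34. Of 17 TCA cycle genes 10 rose, 15 over the list alone (adjusted p = 2.94e-09, but 0.245 with an estimated correlation). They include Pdha1 of pyruvate dehydrogenase (1.26 ± 0.22). Of 17 genes of BCAA catabolism 7 rose, 10 over the list alone (adjusted p = 2.16e-06, but 0.177 with an estimated correlation), with Bckdha at 1.94 ± 0.26. Glycogen genes had 10 of 17 up, 12 over the list alone (adjusted p = 1.49e-08, but 0.0804 with an estimated correlation), with Gys1 at 1.31 ± 0.18. Glycolysis and glucose uptake genes had 4 of 19 up, 7 over the list alone (adjusted p = 0.000637, but 0.467 with an estimated correlation).

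Of 17 ubiquitin ligases and FoxO atrophy genes 8 rose in Crtc2 muscle, 12 over the list alone (adjusted p = 8.72e-14, and 0.0116 with an estimated correlation). Trim63 rose by 1.83 ± 0.33, Klf15 by 2.27 ± 0.30 and Ddit4 by 2.66 ± 0.40. Of 23 autophagy and lysosome genes 12 rose, 13 over the list alone (adjusted p = 1.74e-08, and 0.0124 with an estimated correlation). They include Gabarapl1 (1.62 ± 0.26) and Wipi1 (1.49 ± 0.25) of the autophagosome. Of 15 glucocorticoid targets 8 rose, with 8 up and 1 down over the list alone (adjusted p = 1.5e-06, but 0.063 with an estimated correlation). Klf9 rose by 2.70 ± 0.28 and Fkbp5 by 3.21 ± 0.60. CREB and CRTC targets went both ways, with 3 of 24 up and 2 down, as over the list alone. Their median was 0.06 with TMM and -0.26 when scaled by library totals (adjusted p = 0.33, and 0.438 with an estimated correlation). Pde4d rose by 3.20 ± 0.25, the clock gene Per1 by 1.51 ± 0.34 and Irs2 by 2.76 ± 0.88, while Id1 fell by 1.85 ± 0.43 and Egr1 by 2.12 ± 0.58. Without ADF Crtc2 replicate 1 the adjusted p of Irs2 was 0.175, without Fed Crtc2 replicate 1 that of Id1 was 0.0553, and without Fed Crtc2 replicate 2 that of Egr1 was 0.104. Oxidative phosphorylation had 11 of 48 members up and 1 down, with 13 and 3 over the list alone, and did not pass (median 0.10, and -0.22 when scaled by library totals; adjusted p = 0.0507, and 0.834 with an estimated correlation). Sdha rose by 1.26 ± 0.18.

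Antigen presentation and interferon response genes were lower as lists under ADF in Crtc2 muscle, while macrophage (adjusted p = 0.184) and B cell markers (0.62) did not pass. Of 14 antigen presentation genes 6 fell, 7 over the list alone (median -1.17, adjusted p = 2.46e-06, but 0.348 with an estimated correlation). Among them were B2m, the light chain of class I molecules (-1.20 ± 0.20), H2-K1 (-1.80 ± 0.36) and the transactivator Nlrc5 (-3.36 ± 0.51). Of 19 interferon response genes 5 fell, 9 over the list alone (median -2.01, adjusted p = 2.03e-06, but 0.245 with an estimated correlation), with the GTPase Gbp3 at -2.25 ± 0.38. Of 13 T and NK cell markers 1 fell, Cd3g, and 7 over the list alone (median -4.33, or -3.46 with genes at 0 set to their bound; adjusted p = 0.000851, but 0.438 with an estimated correlation). Of 17 regeneration and denervation genes 4 fell, 8 over the list alone (adjusted p = 0.000207, but 0.0949 with an estimated correlation). The embryonic myosin Myh3 fell by 1.83 ± 0.50. Of 11 endothelial markers Kdr (-1.57 ± 0.32) and Esam (-1.13 ± 0.29) fell, 4 over the list alone (adjusted p = 0.015, but 0.438 with an estimated correlation). Of 19 cell cycle genes Cdk1 and Top2a (-4.18 ± 1.08) fell, 3 over the list alone (median -2.78, or -1.81 at the bounds; adjusted p = 0.0107, but 0.467 with an estimated correlation). Of 10 slow fibre genes 2 fell, 6 over the list alone (adjusted p = 0.0128, but 0.331 with an estimated correlation), with troponin Tnnt1 at -2.18 ± 0.38. Leaving out Fed Crtc2 replicate 2 ended the calls of the cell cycle list (adjusted p = 0.072) and the slow fibre list (0.0627). The adjusted p of Myh3 was 0.139 and that of Cdk1 0.0614 without ADF Crtc2 replicate 1. That of Top2a was 0.0868 without ADF Crtc2 replicate 3, and that of Esam 0.0742 without ADF Crtc2 replicate 2.

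Large rises under ADF in Crtc2 muscle were in Pm20d2 (5.61 ± 1.46), Ccdc85c (5.51 ± 1.41) and the translation repressor Eif4ebp2, which rose 30.3-fold, from 2.5 ± 1.72 to 76.2 ± 17.6 CPM. Pdpr, a regulatory subunit of pyruvate dehydrogenase phosphatase, rose by 4.09 ± 0.66, Cep85l by 3.59 ± 0.38 and Ston2 by 3.51 ± 0.51. Klhl34 (4.77 ± 1.34), the phosphatase Phospho1 (4.30 ± 1.21) and Lmbrd2 (4.18 ± 1.28) rose too. At 0 counts in all ADF Crtc2 libraries were Cd46 (at least 65.5-fold lower), the neutrophil gene S100a8 (61.3), Spag1 (56.9), Tnfrsf4 (54.3), Cd3g (52.7), Mov10 (43.2), Vsig2 (41.6), Dgat2l6 (38.5) and Acap1 (35.5). Oas2, an antiviral enzyme, had 2 counts under ADF and 1159 in fed libraries. Among genes with a mean of 1 to 3 CPM, 21.6 to 30.1% of values were 0 in the ADF Crtc2 libraries. In fed Crtc2 replicates 1, 2 and 3 it was 35.9, 4.8 and 6.7%. Detection of low genes thus differed between these libraries, and its part in the genes at 0 was not tested. Neat1 fell 9.62-fold and Rsrp1 9.7-fold here too, genes looked up in Crtc2 muscle after their values in GFP muscle were seen. Without ADF Crtc2 replicate 1 the adjusted p was 0.073 for Pm20d2, 0.0975 for Vsig2 and 0.102 for Dgat2l6. It was 0.0797 for S100a8 without Fed Crtc2 replicate 1, 0.171 for Phospho1 without Fed Crtc2 replicate 2, and 0.141 for Klhl34 and 0.108 for Lmbrd2 without Fed Crtc2 replicate 3. In total 1758 genes passed, 1009 higher (57.4%) and 749 lower. Of these 1253 changed at least 2-fold. Scaled by library totals, with a shift of the median by -0.321, 502 of 1930 were higher (26%), and with DESeq2 1264 of 2811 (45%) and a filter at a mean of 10 CPM 946 of 1892 (50%). Without ADF Crtc2 replicate 1 the count was 1129. Nr4a3 (1.42 ± 0.93), Nr4a1 (0.03 ± 0.24), Ppargc1a (0.56 ± 0.38), Sik1 (0.09 ± 0.40), Cpt1b (0.48 ± 0.52), Angptl4 (1.15 ± 1.17), Fasn (0.45 ± 0.47), Adipoq (2.34 ± 1.90), Igf1 (-0.93 ± 0.84), Myh7 (-0.15 ± 0.84), Myh4 (0.02 ± 0.37), Mki67 (-3.98 ± 1.28) and Crtc2 (-0.81 ± 0.27) did not pass.

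The responses to ADF with the 2 vectors shared 473 genes that rose (41 expected by chance) and 288 that fell (22.9 expected), and 1 gene passed in opposite directions. Pdk4, Fbxo32, Pnpla2, Acadvl and Gys1 are among the genes that rose with both vectors, and Neat1 and Rsrp1 among those that fell. Across the 7789 genes with a mean of at least 10 CPM, Pearson's r between the log2 fold changes was 0.718 and Spearman's rho 0.668, over genes, which are not independent replicates. Of the 1758 genes that passed in Crtc2 muscle, 1677 (95.4%) had the same sign in GFP muscle.

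**Figure D2:**
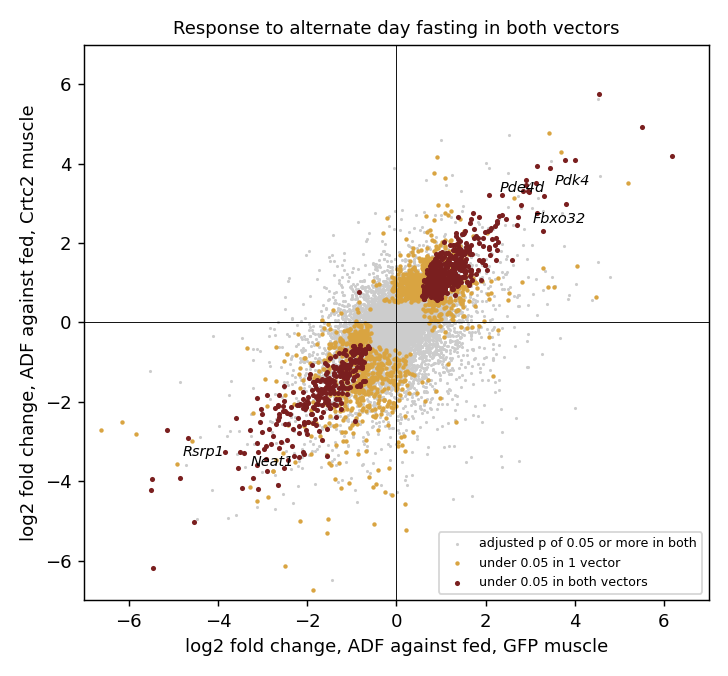
Log2 fold change of ADF against fed in GFP muscle (horizontal axis) and Crtc2 muscle (vertical axis). Each point is a gene with a mean of at least 2 CPM over the 2 groups with each vector. Points beyond the axis limits are not shown. Pearson's r was 0.718 over the 7789 genes with a mean of at least 10 CPM, which is not the set of genes drawn.

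**Figure D3:**
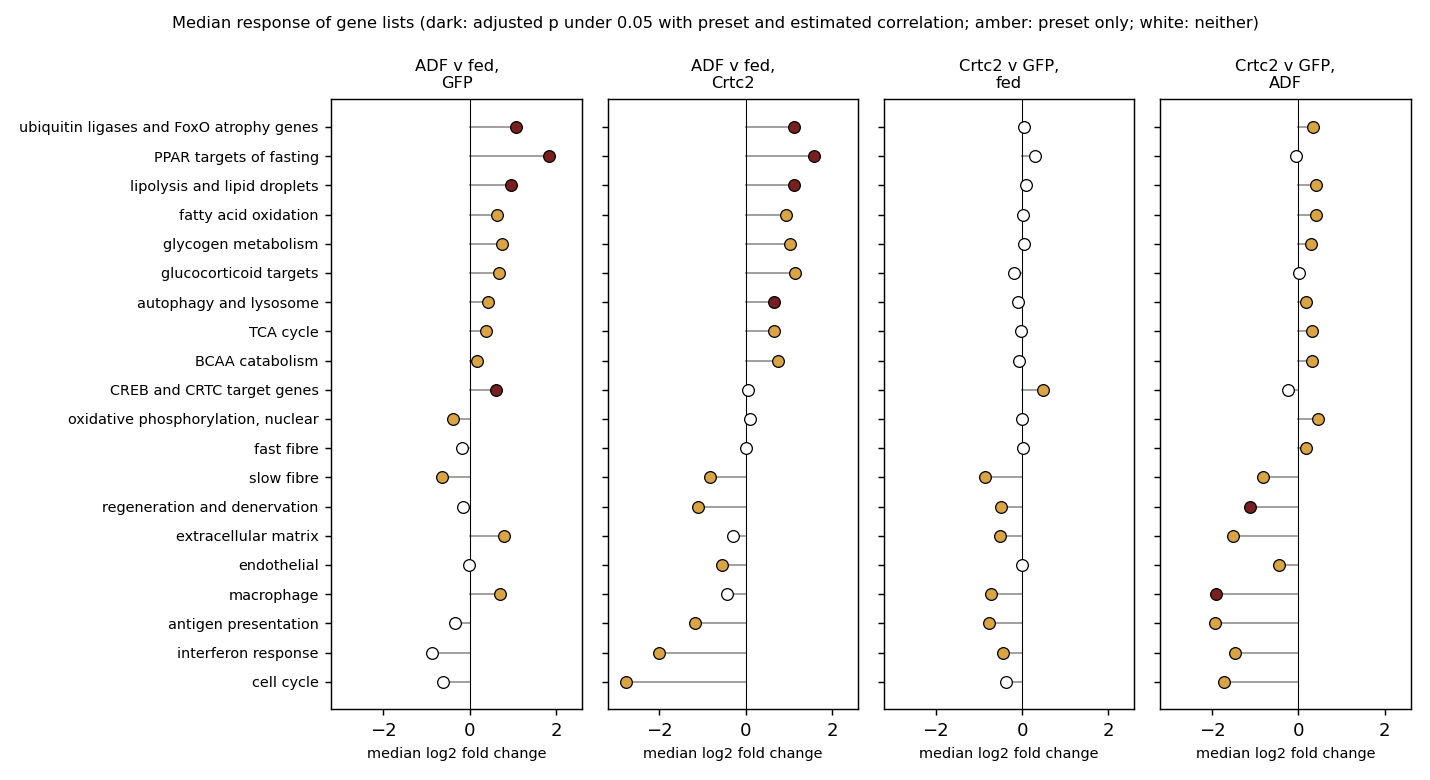
Median log2 fold change of 20 gene lists in the 4 comparisons of 2 groups. Fatty acid oxidation lay at 0.64 and 0.92 in the ADF comparisons and at 0.03 and 0.41 in those of Crtc2 against GFP, and antigen presentation at -0.76 in fed and -1.94 in ADF muscle for Crtc2 against GFP.

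The comparison of Crtc2 with GFP in fed muscle asks what the vector changes without fasting. Crtc2 (chromosome 3, 90254163 to 90264125) was at 67.0 ± 10 CPM in Crtc2 and 23.5 ± 5.97 CPM in GFP muscle, 2.85-fold (1.51 ± 0.28), with no overlap between the libraries, but an adjusted p of 0.134. The other 6 tested members of the CRTC and CREB family had positive fold changes as well, Crtc1 (1.08 ± 0.54), Crtc3 (1.02 ± 0.38), Atf1 (0.83 ± 0.46), Creb1 (0.53 ± 0.43), Crebbp (0.26 ± 0.30) and Ep300 (0.26 ± 0.35). The list passed (median 0.83; 0 of 7 members past the threshold, 2 up over the list alone; adjusted p = 2.48e-05, and 0.048 with an estimated correlation). Without Crtc2 its unadjusted p was 0.000774, and 0.00875 with an estimated correlation. The CREB and CRTC target genes were higher as a list, with 0 of 24 past the threshold and 1 up and 1 down over the list alone (median 0.49, adjusted p = 0.00175, but 0.0841 with an estimated correlation). Among the members with positive fold changes were Irs2, at 0 in fed GFP and 1.24 ± 1.09 CPM in fed Crtc2 muscle (adjusted p = 0.134), the nuclear receptors Nr4a3 (2.40 ± 0.98) and Nr4a1 (0.50 ± 0.24), and Crem (1.72 ± 0.72). Ppargc1a (-0.02 ± 0.38) and Sik1 (-0.26 ± 0.40) had negative fold changes. Among genes with a mean of 1 to 3 CPM, 12.1 to 32.7% of values were 0 in the fed GFP libraries. In fed Crtc2 replicates 1, 2 and 3 it was 35.9, 4.8 and 6.7%. The part of detection in the higher values of low genes such as Irs2 was not tested. In total 0 genes passed in edgeR and 0 in limma-voom, with 81 in DESeq2. An unadjusted p under 0.05 was found for 871 where 800 are expected by chance, and the smallest adjusted p was 0.134. The count was 18 without Fed GFP replicate 2, 12 without ADF GFP replicate 3, 5 without Fed Crtc2 replicate 3 and 2 without ADF GFP replicate 2.

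Some immune and matrix lists were lower in fed Crtc2 than in fed GFP muscle, though 0 of their members passed over all genes. T and NK cell (adjusted p = 0.153), neutrophil (0.763), fibroblast (0.0857) and tendon markers (0.101) did not pass. B cell markers had a median of -2.52, with 2 of 8 down over the list alone (adjusted p = 8.32e-09, but 0.136 with an estimated correlation). Igkc, the kappa light chain, averaged 9.03 ± 6.35 in Crtc2 and 1530 ± 502 CPM in GFP muscle, and Jchain 1.24 ± 0.71 and 108 ± 72.5 CPM. Antigen presentation had a median of -0.76, with 3 of 14 down over the list alone (adjusted p = 3.95e-08, but 0.349 with an estimated correlation). B2m was at -1.07 ± 0.20 and H2-K1 at -1.08 ± 0.35. Macrophage markers (-0.73; 1 of 15 down over the list alone; adjusted p = 0.000738, but 0.259 with an estimated correlation), with C1qc at -1.0 ± 0.30, were lower too. So were interferon response (-0.45; 0 of 19; 0.000738, but 0.509 with an estimated correlation) and extracellular matrix (-0.50; 0 of 21; 0.00021, but 0.729 with an estimated correlation). Slow fibre genes had a median of -0.87, with 1 of 10 up and 1 down over the list alone (adjusted p = 0.000375, but 0.259 with an estimated correlation). Myl3 was at 1.54 ± 0.47 and Tnnc1 at -1.53 ± 0.63. Regeneration and denervation genes (-0.50; 2 of 17 down over the list alone; adjusted p = 0.0103, but 0.349 with an estimated correlation), with Tnnt2 at -1.50 ± 0.37 and Myl4 at -1.10 ± 0.26, were lower as well. Smooth muscle and pericyte markers (-0.48; 0 of 7; 0.00779, but 0.509 with an estimated correlation) and endoplasmic reticulum chaperones (-0.29; 0 of 16; 0.0461, but 0.509 with an estimated correlation) completed the 9 lower lists. With 1 library left out, the adjusted p reached 0.388 for the matrix (without Fed GFP replicate 3), 0.316 for regeneration (without Fed Crtc2 replicate 3). It reached 0.221, 0.106 and 0.0889 for smooth muscle, interferon and slow fibre (without Fed GFP replicate 1) and 0.182 for the chaperones (without Fed GFP replicate 2). Pdk4 (0.71 ± 0.47), Angptl4 (0.43 ± 1.16), Ucp3 (0.32 ± 0.30), Cpt1b (0.43 ± 0.52), Lpl (0.36 ± 0.20), Fbxo32 (0.18 ± 0.26), Trim63 (0.05 ± 0.32), Igf1 (-0.72 ± 0.83), Fasn (-0.30 ± 0.46), Gys1 (0.36 ± 0.17), Myh7 (-1.05 ± 0.85), Myh4 (-0.29 ± 0.37), Adipoq (-1.99 ± 1.88), Mki67 (-1.07 ± 1.13) and Myh3 (-0.67 ± 0.48) did not pass.

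Under ADF, Crtc2 muscle had lower levels of most immune lists than GFP muscle, while the 4 neutrophil markers did not pass (median 0.56, adjusted p = 0.884; 2 positive and 2 negative). B2m fell 3.68-fold, from 551 ± 96.6 in GFP to 150 ± 18.8 CPM in Crtc2 muscle (-1.88 ± 0.20, adjusted p = 0.000122). Of 14 antigen presentation genes 5 fell, 12 over the list alone (median -1.94, adjusted p = 6.92e-25, but 0.0767 with an estimated correlation). The class I gene H2-K1 was at -2.26 ± 0.37, H2-D1 at -1.88 ± 0.35, the class II gene H2-Ab1 at -2.19 ± 0.38 and Tapbp at -1.32 ± 0.28. Of 15 macrophage markers 6 fell, 10 over the list alone (median -1.90, adjusted p = 1.59e-19, and 0.0122 with an estimated correlation). Among them were Tyrobp, an immune receptor adaptor (-2.32 ± 0.37), Csf1r, the receptor of macrophage growth factor (-2.0 ± 0.33), complement C1qc (-1.63 ± 0.30), Ctss (-2.0 ± 0.36), Lyz2 (-1.06 ± 0.21) and Cd68 (-2.0 ± 0.40). Of 19 interferon response genes 2 fell, Gbp3 (-2.38 ± 0.38) and Gbp2 (-1.97 ± 0.36), and 7 over the list alone (median -1.46, adjusted p = 7.91e-15, but 0.0817 with an estimated correlation). Of 13 T and NK cell markers 1 fell, 11 over the list alone (median -4.63, or -4.41 at the bounds; adjusted p = 6.62e-14, but 0.0945 with an estimated correlation). Of 8 B cell markers 1 fell, Cd79b, and 5 over the list alone (median -6.12, or -4.57 at the bounds; adjusted p = 1.72e-05, but 0.207 with an estimated correlation). The B cell median was -2.68 without ADF GFP replicate 3. At 0 counts in Crtc2 muscle were the immunoglobulin genes Ighv8-12 (at least 163-fold lower) and Igkv3-2 (129), the T cell receptor chain Cd3g (41.1) and the RNA helicase Mov10 (37.1). Igkv8-21 had 1 count in Crtc2 and 2813 in GFP muscle, Ly6c2 had 4 and 2451, and Igha had 6 and 1394. Among genes with a mean of 1 to 3 CPM, 21.6 to 30.1% of values were 0 in the ADF Crtc2 libraries. In the ADF GFP libraries it was 5.9 to 19.4%. Detection of low genes thus differed between the groups compared, and its part in the genes at 0 was not tested. Adcy7 fell by 5.31 ± 0.91, the chemokine Cxcl16 by 3.96 ± 0.86 and the cytokine receptor Il2rg by 3.67 ± 0.79. Summed immunoglobulin constant genes were at 382 to 8396 CPM in the 6 GFP libraries and 30.3 to 157 CPM in the 6 Crtc2 libraries, and ADF GFP replicate 3 had the highest value.

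Matrix, regeneration and slow fibre genes were lower in the same comparison. All 21 extracellular matrix genes had negative fold changes (median -1.50, and -1.68 when scaled by library totals). Of these 3 fell, 15 over the list alone (adjusted p = 4.06e-22, but 0.0945 with an estimated correlation): the gelatinase Mmp2 (-1.73 ± 0.25), the proteoglycan Bgn (-1.40 ± 0.23) and fibronectin Fn1 (-1.70 ± 0.36). Of 10 fibroblast markers 0 passed, 4 fell over the list alone (median -0.87, adjusted p = 5.62e-05, but 0.0945 with an estimated correlation). Of 8 tendon markers Thbs4 fell (-1.38 ± 0.22), 3 over the list alone (adjusted p = 0.00377, but 0.316 with an estimated correlation). Of 17 regeneration and denervation genes 3 fell, 8 over the list alone (median -1.13, adjusted p = 1.3e-10, and 0.0277 with an estimated correlation). They were the embryonic light chain Myl4 (-1.41 ± 0.26), the fusion protein Mymk (-2.80 ± 0.56) and the transcription factor Myog (-1.83 ± 0.42). Of 10 slow fibre genes 2 fell, 3 over the list alone (median -0.83, adjusted p = 2.6e-05, but 0.0996 with an estimated correlation). They were Tnni1 (-1.67 ± 0.33) and Tnnt1 (-1.66 ± 0.38). Of 19 cell cycle genes 0 passed, 2 fell over the list alone (median -1.72, or -1.63 at the bounds; adjusted p = 1.72e-05, but 0.214 with an estimated correlation). Endothelial (median -0.44; 1 of 11 down over the list alone; adjusted p = 0.00373, but 0.306 with an estimated correlation), smooth muscle and pericyte (-0.72; 1 of 7; 0.0288, but 0.345 with an estimated correlation) and erythroid markers (-1.27; 0 of 6; 0.0147, but 0.312 with an estimated correlation) were lower as lists. Igfbp5, which binds insulin-like growth factors, fell by 1.08 ± 0.24 and Ucp2 by 1.6 ± 0.33. Without ADF GFP replicate 2 the adjusted p was 0.0943 for smooth muscle and 0.0595 for endothelial markers, and without ADF Crtc2 replicate 2 it was 0.129 for erythroid markers.

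Mitochondrial genes were higher as lists in ADF Crtc2 than in ADF GFP muscle, by small amounts. All 48 nuclear genes of oxidative phosphorylation had positive fold changes (median 0.46, or 0.30 when scaled by library totals). Of these 0 passed over all genes and 35 rose over the list alone (adjusted p = 1.27e-25, but 0.141 with an estimated correlation). Uqcrq of complex III was at 0.77 ± 0.18 (adjusted p = 0.055), Cox7b at 0.69 ± 0.18, cytochrome c, Cycs, at 0.67 ± 0.18 and Ndufa4 at 0.67 ± 0.17. Log2 fold changes in this comparison fell with gene length (Spearman's rho -0.19 over genes with a mean of at least 10 CPM). The part of length is weighed in the closing section for oxidative phosphorylation and was not tested for the lists that follow. Fatty acid oxidation genes had a median of 0.41 (24 of 24 positive, 2 up over the list alone; adjusted p = 3.36e-09, but 0.227 with an estimated correlation), with Eci1 at 0.73 ± 0.21. TCA cycle genes had a median of 0.31 (17 of 17 positive, 0 over the list alone; 1.08e-06, but 0.276 with an estimated correlation), with Idh3b at 0.54 ± 0.16. BCAA catabolism (0.32; 0.000418, but 0.227 with an estimated correlation) and glycogen metabolism (0.30; 0.00114, but 0.227 with an estimated correlation) were higher as lists with 0 members up. The same holds for glycolysis (0.29; 1 of 19 down over the list alone, Hk1 at -1.49 ± 0.41; 0.00151, but 0.419 with an estimated correlation), lipolysis (0.41; 0.0113, but 0.207 with an estimated correlation) and atrophy genes (0.33; 0.0113, but 0.227 with an estimated correlation). Schwann cell markers (1.19; 0.0147, but 0.419 with an estimated correlation) and fast fibre genes (0.19; 0.0232, but 0.462 with an estimated correlation) were higher as lists too. So were autophagy (0.19; 0.0424, but 0.227 with an estimated correlation) and the proteasome (0.15, but -0.02 when scaled by library totals; 0.0147, but 0.278 with an estimated correlation). When scaled by library totals, which moves the median of all genes by -0.169, the medians were 1.02 for Schwann cell markers, 0.25 for lipolysis, 0.24 for fatty acid oxidation, 0.16 for atrophy genes, 0.15 for the TCA cycle and BCAA catabolism, 0.135 for glycolysis, 0.12 for glycogen metabolism, 0.03 for fast fibre and 0.01 for autophagy. The 7 named rises were Nmnat1, the nuclear enzyme of NAD synthesis (1.23 ± 0.26), Ggnbp1 (1.14 ± 0.26), the lipid transfer protein Stard10 (1.05 ± 0.23), the acylphosphatase Acyp2 (0.89 ± 0.17), Mlf1 (0.82 ± 0.19), Chchd3 of the mitochondrial cristae (0.75 ± 0.17) and Ndufc1 of complex I (0.70 ± 0.16). Leaving out 1 library took the adjusted p to 0.209 for atrophy genes, 0.162 for autophagy and 0.149 for the proteasome (ADF Crtc2 replicate 1). It reached 0.201 for fast fibre (ADF GFP replicate 2), 0.282 for Schwann cell (ADF Crtc2 replicate 2) and 0.0617 for lipolysis (ADF GFP replicate 3). Crtc2 was at 38.3 ± 6.06 in Crtc2 and 19.8 ± 3.75 CPM in GFP muscle, 1.93-fold (0.95 ± 0.28, adjusted p = 0.127).

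**Figure D4:**
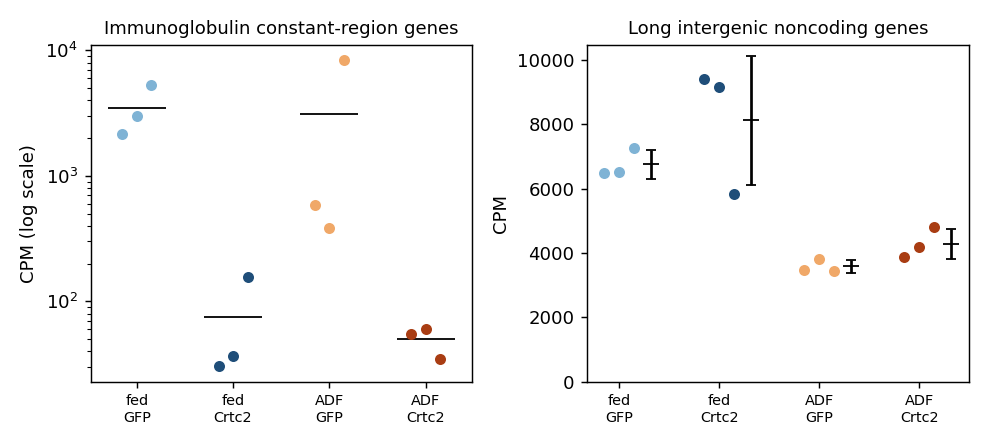
Summed CPM of immunoglobulin constant genes (log axis) and of long intergenic noncoding genes (linear axis from 0) in each of the 12 libraries, with the mean of each group as a line. The 6 GFP libraries lay between 382 and 8396 CPM for immunoglobulin constant genes and the 6 Crtc2 libraries between 30.3 and 157 CPM; for noncoding genes the ADF libraries lay between 3444 and 4799 CPM and the fed libraries between 5821 and 9416 CPM.

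In total 116 genes passed between Crtc2 and GFP muscle under ADF, 12 higher and 104 lower. Of these 104 differed at least 2-fold. Scaled by library totals, 157 passed, 4 of them higher. With a filter at a mean of 10 CPM, 144 passed, 23 of them higher. How far the larger share of values at 0 in the ADF Crtc2 libraries feeds the split by direction was not tested. The count of 116 fell to 25 without ADF GFP replicate 3 and to 25 without ADF Crtc2 replicate 1. It was 51 without ADF Crtc2 replicate 3 and 69 without ADF GFP replicate 1. Of the 42 named genes that passed, 8 kept an adjusted p under 0.05 whichever library was left out: B2m, Tyrobp, Csf1r, Mmp2, Bgn, Gbp3, Thbs4 and Mov10. Of the other 34, 33 lost the call without ADF Crtc2 replicate 1 (adjusted p from 0.0513 to 0.27), 30 without ADF GFP replicate 3 (0.0559 to 0.339) and 24 without ADF Crtc2 replicate 3 (0.0502 to 0.248). The call of 21 was lost without ADF Crtc2 replicate 2 (0.0509 to 0.202), 17 without ADF GFP replicate 1 (0.0513 to 0.143) and 12 without ADF GFP replicate 2 (0.0661 to 0.151). Leaving out a fed library, which is in neither group compared, ended between 2 and 6 of these calls, with adjusted p up to 0.0885. Pdk4 (0.60 ± 0.46), Ucp3 (0.61 ± 0.30), Lpl (0.66 ± 0.20), Fbxo32 (0.33 ± 0.26), Trim63 (0.43 ± 0.32), Gys1 (0.10 ± 0.17), Ppargc1a (0.03 ± 0.38), Nr4a1 (-0.08 ± 0.24), Nr4a3 (-0.23 ± 0.91), Sik1 (-0.40 ± 0.40), Angptl4 (-0.35 ± 1.15), Cpt1b (0.08 ± 0.52), Igf1 (-1.56 ± 0.85), Fasn (-0.71 ± 0.47), Myh7 (-1.0 ± 0.85), Myh4 (0.01 ± 0.37), Adipoq (-1.54 ± 1.84), Mki67 (-3.82 ± 1.27) and Myh3 (-1.37 ± 0.49) did not pass.

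The responses to Crtc2 in the 2 diets shared 0 genes past the adjusted threshold, since 0 passed in fed muscle in edgeR. Of the 116 genes that passed under ADF, 96 (82.8%) had the same sign in fed muscle, and across 7789 genes Pearson's r was 0.44 and Spearman's rho 0.11. At an unadjusted p under 0.01, 31 genes were lower with Crtc2 in both diets (1.92 expected by chance, odds ratio 30, Fisher's exact p = 3.76e-30), 1 was higher (1.06 expected) and 3 went in opposite directions. Fisher's p is over genes, which are not independent replicates, and does not measure the spread between libraries.

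The diet by vector interaction asks whether the response to Crtc2 differs between diets, or equally whether the response to ADF differs between vectors. For 0 of the 16007 genes did it pass in edgeR, and for 0 in limma-voom and 181 in DESeq2. Of all genes 1240 had an unadjusted p under 0.05, where 800 are expected. The smallest adjusted p, 0.174, belonged to Irs2 and Cd3g, each with a group at 0, for which no size is given. Irs2 was at 0 in fed GFP, 1.24 ± 1.09 in fed Crtc2, 12.7 ± 3.71 in ADF GFP and 8.44 ± 2.41 CPM in ADF Crtc2 muscle, and Cd3g at 4.60 ± 1.12, 6.23 ± 5.71, 4.86 ± 2.93 and 0 CPM. Gbp3 followed (-2.16 ± 0.51, adjusted p = 0.315). As lists, oxidative phosphorylation (median 0.43, 48 of 48 positive; adjusted p = 1e-17, but 0.368 with an estimated correlation) and fatty acid oxidation (0.36; 2.84e-06, but 0.385 with an estimated correlation) had positive medians. Oxidative phosphorylation had a median under ADF of -0.38 in GFP muscle (-0.55 when scaled by library totals) and of 0.10 in Crtc2 muscle, where it did not pass (-0.22 when scaled by library totals). Over genes with a mean of at least 10 CPM, the interaction fell with gene length (Spearman's rho -0.159). The part of length in these list medians was not tested. Cycs was at 0.80 ± 0.25, Cox7b at 0.79 ± 0.25 and Acadvl at 0.90 ± 0.32. Macrophage markers (-1.26; 4 of 15 down over the list alone; 2.84e-06, but 0.173 with an estimated correlation) and antigen presentation genes (-1.22; 3 of 14; 1.17e-05, but 0.385 with an estimated correlation) had negative medians. Antigen presentation had negative medians under ADF with both vectors (-0.35 in GFP, where it did not pass, and -1.17 in Crtc2 muscle). Fcgr3 was at -2.39 ± 0.74, Ctss at -1.75 ± 0.50 and H2-Ab1 at -1.69 ± 0.52. CREB and CRTC targets had a median of -0.63 (0.00541, but 0.173 with an estimated correlation; 0.015 with fry), with Nr4a3 at -2.63 ± 1.33 and Egr1 at -2.12 ± 0.80, and Pde4d the other way at 1.13 ± 0.33. Of the 41 lists 19 passed with the preset correlation, 0 with an estimated correlation and 3 with fry. Crtc2 itself was at -0.56 ± 0.39 (adjusted p = 0.764), and the other genes named in advance had adjusted p between 0.67 and 1. The call of 7 of the 19 lists ended with 1 library left out, with an adjusted p of up to 0.464.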

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

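The gene lists in the next paragraph passed a test of the difference between fed and ADF muscle in their response to Crtc2 with the preset correlation, but 0 of the 19 passed with an estimated correlation; the patterns weighed after it are differences between vectors or diets. The interaction test, the length and expression test of the oxidative phosphorylation genes and the counts over other splits of the libraries were chosen before the results were seen; the tests of blood, muscle fibre share, the highest library, the immune reaction, GC content, noncoding gene length, library preparation and fibre RNA share were chosen after, and the last was changed in form after a first result was seen.

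Of 41 gene lists 19 responded differently to Crtc2 under ADF and in fed muscle with the preset correlation, with 0 of 16007 genes past the threshold (edgeR; 1240 at an unadjusted p under 0.05, 0 in limma-voom, 181 in DESeq2). The differences of the median log2 response were negative for T and NK cell markers (-4.19), cell cycle (-1.70), macrophage markers (-1.26), antigen presentation (-1.22), regeneration and denervation (-1.17), interferon response (-1.13), extracellular matrix (-1.02), CREB and CRTC targets (-0.63), the CRTC and CREB family (-0.62) and endothelial markers (-0.54). The medians of T and NK cell and cell cycle genes include fitted values of genes at 0 and are no bounds. The differences were positive for Schwann cell markers (2.29), oxidative phosphorylation (0.43), BCAA catabolism (0.40), fatty acid oxidation (0.36), the TCA cycle (0.30), ubiquitin ligases and FoxO atrophy genes (0.28), autophagy (0.22), glycolysis (0.22) and the proteasome (0.18). Over genes with a mean of at least 10 CPM, the interaction fell with gene length (Spearman's rho -0.159), and the part of length in these lists was not tested. When scaled by library totals the positive ones were 0.289 for oxidative phosphorylation, 0.252 for BCAA catabolism, 0.189 for fatty acid oxidation, 0.147 for the TCA cycle, 0.095 for atrophy genes, 0.081 for autophagy, 0.063 for glycolysis, 0.019 for the proteasome and 2.165 for Schwann cell markers. With an estimated correlation 0 of the 19 passed (adjusted p from 0.173 to 0.57), and with fry 3 did. Crtc2 itself was raised less over GFP under ADF than in fed muscle. Its interaction did not pass, but the rises of Crtc2 compared may not be equal. Leaving out 1 library ended 7 of the calls, with an adjusted p of 0.464 for glycolysis (without Fed Crtc2 replicate 2), 0.262 for endothelial markers (without Fed GFP replicate 2), 0.118 for the CRTC and CREB family (without Fed Crtc2 replicate 3) and 0.0769 for Schwann cell markers (without Fed GFP replicate 1). Without ADF Crtc2 replicate 1 it was 0.26 for atrophy genes, 0.154 for the proteasome and 0.05 for autophagy. Of 100 arrangements of the vector labels within diets, 100 called as many genes as the real one, which called 0. A real count of 0 fixes this outcome, so it says nothing on chance; the highest other arrangement called 71, and why was not tested.

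Summed immunoglobulin constant genes were 58.1-fold lower in Crtc2 than in GFP muscle when fed and 25.4-fold lower under ADF. Macrophage and antigen presentation genes were lower as lists with the preset correlation in both diets, but with an estimated correlation their adjusted p was 0.259 and 0.349 in fed muscle, where 0 of 15 and 0 of 14 members passed, and 0.0122 and 0.0767 under ADF. T and NK cell markers did not pass in fed muscle (adjusted p = 0.153), and neutrophil markers passed in neither diet (0.763 in fed and 0.884 in ADF muscle). Without ADF GFP replicate 3 the ADF fold was 9.74, without ADF GFP replicate 2 it was 45.7, and without Fed Crtc2 replicate 3 the fed fold was 97. Blood left in the muscle as the whole source of the immunoglobulin genes is argued against, since their constant genes were above hemoglobin genes in 6 of 6 GFP libraries. Erythroid markers were lower too under ADF (median -1.27, adjusted p = 0.0147, but 0.312 with an estimated correlation), so a difference in blood content as a part stays open. A lower share of muscle fibres in GFP muscle as the whole cause is argued against by macrophage markers lying below endothelial markers by 1.46 (difference of medians -1.46, 95% interval -1.69 to -1.17), and ADF GFP replicate 3 as the only source by a macrophage median of -1.65 without it (adjusted p = 0.00662 with an estimated correlation). A candidate explanation that stays open is an immune reaction to the GFP vector or its product that Crtc2 muscle lacks: the vectors separate within both diets (exact p = 0.005 over 400 arrangements, the smallest they can give), which any cause tied to the vector would also give. No untransduced muscle was analysed here, so a reaction in GFP muscle and an effect of Crtc2 on immune cells cannot be told apart.

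Of 326 long intergenic noncoding genes 15 fell, Neat1 among them, and 3 rose under ADF in GFP muscle (median -0.82), and 19 fell and 1 rose in Crtc2 muscle (-1.02), while most did not pass. Antisense genes had medians of -0.60 and -0.97 (6 fell and 2 rose in GFP, 7 fell and 4 rose in Crtc2 muscle). The medians were -3.34 and -5.60 for 14 small nucleolar RNA genes, of which 0 passed. For 165 genes of the annotation class TEC they were -1.67 and -1.94 (3 fell and 0 rose, and 2 fell and 1 rose). The 1156 processed pseudogenes were not lower by their medians (0.003 and 0.27). Against protein-coding genes matched on expression and GC content, long intergenic noncoding genes were lower by a median of -0.74 (95% interval -1.06 to -0.46), and against genes matched on expression and length by -0.66 (-0.89 to -0.38), so neither GC content nor length is the whole cause. Library preparation that followed the diets stays open, since 6 of 6 ADF libraries lay below every fed library in the sum of these genes and the labels name 2 preparation kits without assigning them. Fasting and a difference in preparation or RNA extraction cannot be told apart here, and either may be the source.

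Oxidative phosphorylation genes were higher as a list in Crtc2 than in GFP muscle under ADF (median 0.462). Their median lay above 100% of 10000 lists matched on length and expression, which argues against these as the whole cause, but the matched lists themselves had a median of 0.312 (95% interval 0.23 to 0.37), so a large part of the shift is shared with genes of like length and expression. A larger share of fibre RNA as the whole cause is argued against by a median 0.22 above that of fast fibre, calcium handling and glycolysis genes (95% interval 0.12 to 0.29), each relative to matched genes. Those fibre genes were themselves higher (median 0.222), but not relative to matched genes (-0.073). Genes matched on expression may be fibre genes too, so a larger share of fibre RNA as a part stays open. An effect of Crtc2 on these genes is a hypothesis that may hold for the rest of the shift, and the list test itself did not pass with an estimated correlation (adjusted p = 0.141).

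The counts of genes were compared with other splits of the same libraries. For Crtc2 against GFP in fed muscle, 10 of 10 splits called as many genes as the real one, an outcome that a real count of 0 fixes, and the highest other called 23, for a reason that was not tested. The real split was the 1 of 10 with the most genes for Crtc2 against GFP under ADF (116, highest other 0), ADF against fed in GFP muscle (1140, 0) and in Crtc2 muscle (1758, 0). With 3 against 3 libraries there are 10 splits, too few for a share under 0.05.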

How the results depend on the processing

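The filter at a mean of 10 CPM, the family without Crtc2 and the list tests with 1 library left out were chosen after seeing the data. Counts past the threshold were within 1.5 times those reported with RLE, upper-quartile and library-total scaling, the filter of 1 CPM, the filter at a mean of 10 CPM and the replicate term, for the 5 comparisons. In the order Crtc2 against GFP in fed muscle (0), under ADF (116), ADF against fed in GFP (1140) and Crtc2 muscle (1758) and interaction (0), DESeq2 gave 81, 692, 1898, 2811 and 181 and limma-voom 0, 68, 1308, 1789 and 0. Without a filter the counts were 58 (fed), 385 (ADF) and 67 (interaction); with spread that is not robust 3 (fed); with only the 6 libraries compared 7 (fed) and 300 (ADF). Leaving out 1 library gave 0 to 18 (18 without Fed GFP replicate 2, 12 without ADF GFP replicate 3, 5 without Fed Crtc2 replicate 3, 2 without ADF GFP replicate 2), 25 to 164 (25 without ADF GFP replicate 3 and without ADF Crtc2 replicate 1, 51 without ADF Crtc2 replicate 3, 69 without ADF GFP replicate 1), 677 to 1230 (677, 711 and 740 without ADF GFP replicates 2, 1 and 3), 1129 to 1940 (1129 without ADF Crtc2 replicate 1) and 0 to 3 (3 without Fed GFP replicate 2, 2 without ADF Crtc2 replicate 2 or 3, 1 without Fed GFP replicate 3). Lists past the threshold (11, 26, 16, 17 and 19) were 1, 2, 4, 4 and 0 with an estimated correlation. It widens the test, the more so where the genes of a list move together. With fry they were 2, 9, 12, 13 and 3. For fed muscle lists past the threshold were 7 to 14 with 1 library left out (7 without Fed GFP replicate 1). The overlap of Crtc2 responses was 32 at an unadjusted p under 0.01. Of 330 pairs of a gene and a comparison in the text, 213 kept direction and side of the threshold throughout; of 7220 recomputed values 383 were weaker, 88 stronger and 14 reversed, and the choice of list members was made after values were seen. With 1 library left out, Crtc2 against GFP in fed muscle ranged from -0.10 (without Fed GFP replicate 1) to 0.84 for Ep300, -0.16 (without Fed Crtc2 replicate 2) to 0.38 for Fbxo32, and -0.28 to 0.43 for Ppargc1a and -0.53 to 0.29 for Sik1 (highest without Fed GFP replicate 3). Under ADF Trim63 ranged from -0.19 (without ADF Crtc2 replicate 1) to 0.75, and its interaction from -0.23 (likewise) to 0.70. ADF against fed ranged from -0.56 to 0.74 (without Fed GFP replicate 1) for Myh7 in GFP muscle and -1.46 to 0.26 (without Fed Crtc2 replicate 2) for Igf1 in Crtc2 muscle. The interaction ranged from -1.37 to 0.35 (without Fed Crtc2 replicate 2) for Igf1 and -1.68 (without ADF Crtc2 replicate 1) to 0.61 for Myh7, and was -1.52 for Myh7 in limma-voom. With library totals ADF against fed in Crtc2 muscle was -0.29 for Nr4a1, -0.15 for Nr1d1 and -0.06 for Crebbp, as this scaling shifts the median by -0.321 (-0.158 for the interaction), and the CRTC and CREB family median there was 0.058 without Crtc2 (-0.147 with it). Apart from these constructions the cause was not tested. At this depth 3 counts correspond to 0.0814 to 0.13 CPM, which limits folds against groups at 0.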

Other observations

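Genes of the clock and of calcium handling changed singly under ADF, and their lists did not pass. The clock gene Per3 fell by 2.01 ± 0.30 in GFP and by 1.97 ± 0.30 in Crtc2 muscle (n = 3 against 3), and Dbp, a clock output gene, by 0.89 ± 0.26 and 1.13 ± 0.26. Nr1d1, a clock repressor, rose by 1.27 ± 0.29 in GFP muscle and did not pass in Crtc2 muscle (0.17 ± 0.28, or -0.15 when scaled by library totals). This difference between vectors did not pass in the interaction test. Cacna1s, the voltage sensor of the muscle calcium channel, rose by 1.30 ± 0.18 and 1.84 ± 0.18, and Ryr1, the calcium release channel, by 1.10 ± 0.19 in both. Sln, an inhibitor of the calcium pump, fell by 0.93 ± 0.28 and 2.48 ± 0.29. In the list of lipogenesis, Acacb, which makes malonyl-CoA at mitochondria, rose by 1.29 ± 0.20 and 1.84 ± 0.20, and Mlxipl, a glucose-sensing transcription factor, fell by 1.51 ± 0.26 and 1.54 ± 0.26. Igfbp5 fell by 1.12 ± 0.24 and 1.80 ± 0.24, and the stress gene Ddit3 by 1.35 ± 0.30 and 1.94 ± 0.30. In GFP muscle the adjusted p was 0.141 for Dbp without ADF GFP replicate 2 and 0.185 for Sln without ADF GFP replicate 3, and in Crtc2 muscle it was 0.0614 for Dbp without Fed Crtc2 replicate 3.

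Lars2, Gm15564, Mir6236 and Malat1 lie outside the rule and were chosen after their values were seen. Lars2, the mitochondrial leucyl-tRNA synthetase, rose from 133 ± 23.8 to 1030 ± 329 CPM in GFP muscle (2.96 ± 0.22) and by 3.32 ± 0.22 in Crtc2 muscle. Gm15564 rose by 2.97 ± 0.30 and 3.28 ± 0.31, and Mir6236 by 3.46 ± 0.32 and 3.90 ± 0.33. Transcripts of Lars2 and Gm15564 share a stretch of 72 nt at 98.6% identity; whether reads from it were counted for either gene was not tested. Malat1, a nuclear noncoding RNA, fell by 2.80 ± 0.29 and 3.07 ± 0.29. For Lars2, Gm15564, Mir6236 and Malat1, too, fasting and a difference in preparation or RNA extraction cannot be told apart.

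Members of the CRTC and CREB family did not pass in the comparisons below. Under ADF, Crtc2 against GFP was -0.04 ± 0.54 for Crtc1, -0.28 ± 0.37 for Crtc3, -0.09 ± 0.43 for Creb1, -0.23 ± 0.45 for Atf1, 0.22 ± 0.30 for Crebbp and 0.04 ± 0.35 for Ep300. ADF against fed in GFP muscle was 0.47 ± 0.54 for Crtc1, 1.15 ± 0.38 for Crtc3, -0.24 ± 0.43 for Creb1, 0.30 ± 0.30 for Crebbp and 1.0 ± 0.35 for Ep300. In Crtc2 muscle it was -0.65 ± 0.54 for Crtc1, -0.15 ± 0.37 for Crtc3, -0.86 ± 0.43 for Creb1, 1.06 ± 0.46 for Atf1, 0.26 ± 0.30 for Crebbp (-0.06 when scaled by library totals) and 0.78 ± 0.35 for Ep300.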
